A study of Mus musculus with 10 samples.

How the data were processed

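Gene expression was measured in mouse liver RNA with 10 Affymetrix arrays, 1 array per RNA sample. At 11 weeks of age, each array held RNA pooled from 3 mice of 1 sex: 2 wild-type pools and 2 Gnmt knockout pools, with 1 female and 1 male pool per genotype. The other 6 arrays held single tissues of aged knockout mice: a dysplastic nodule with adjacent liver, and 2 hepatocellular carcinomas (HCC) with adjacent liver. Each lesion was taken to come from the same mouse as the adjacent liver of the same sex and age. That pairing was inferred from the labels, which give no mouse numbers.

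Per the labels, the authors made labelled RNA from 5 ug of total RNA and computed the values with the Affymetrix GCOS software, whose version and settings are not stated. The deposited values are intensity on a linear scale, 1 signal per probe set. The trimmed mean of each deposited array, with 2% of values left out at each end, was 500, so the arrays had been scaled to a common mean. No detection call or raw image was used here. The table held 45101 probe sets, 64 of them controls, with signals from 0.1 to 122580.

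Gene names came from the gene identifiers of the probe set table provided, of which 34741 of 34945 matched the mouse gene table. A single gene was given for 34945 probe sets, 932 listed several genes and 9211 were not listed. Signals were taken to log2 after adding 16.8, the 20th percentile of all values. Each gene was represented by its probe set with the highest mean, and genes were kept where that mean was above the median of all values, a signal of 91 before the addition. The filter left 11032 of 18193 genes. No probe set overlap between paralogs was resolved, so values of the Cyp2, Cyp3a, Mup, Saa and immunoglobulin genes may include signal from relatives.

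Linear models were fitted to the log2 values with limma 3.58.1 in R 4.3.3, using an intensity trend in the variance prior, and p-values were adjusted by the Benjamini-Hochberg method over the 11032 genes. Genes with an adjusted p below 0.05 were called. Knockout was compared with wild-type at 11 weeks with sex as a term, and females with males with genotype as a term. HCC was compared with adjacent liver over 2 pairs, and all lesions with adjacent liver over 3 pairs, with the mouse as a term. The 3 adjacent livers were compared with the 2 knockout pools of 11 weeks with sex as a term. The fits left 1, 1, 1, 2 and 2 residual degrees of freedom in that order, so the calls rest largely on the spread shared across genes. The nodule was also described alone, with 1 array a side and no test.

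There were 33 gene lists fixed before the data were examined, 11 of them cell type markers, and 27 had at least 5 members past the filter. The lists with fewer members, which were not tested, were the sex chromosome check, T and NK cell, erythroid, pancreatic acinar cell, adipocyte, and lymph node stroma lists. Shifts of the other lists against all other genes were tested with camera in limma at a preset correlation between genes of 0.01, and adjusted over the 27 lists. The same test with an estimated correlation, and fry, which tests each list by itself, were alternatives. In the nodule, each list's median was set against 10000 random lists of the same size, which do not keep the correlation between genes.

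The genes named were chosen by a rule written with the design. It took Gnmt, and in each direction the 10 called genes with the largest log2 difference that moved the same way in every pair. Where fewer than 5 were called in a direction, it took the 10 largest that moved by at least 1 log2 unit the same way in every pair, given as values that did not pass. It added up to 4 members per list with the largest differences, and the 10 largest in each direction in the nodule. Clone and prediction names were counted, not named. Clock genes were chosen after their values were seen, as were the acute phase signals given per array.

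The procedure was tested on simulated data with the same designs and 11032 genes, 20 simulations per comparison. For the genotype comparison it recovered 68.2% of genes changed 4-fold and 7.7% of those changed 2-fold, and 10.3% of its calls were false. For HCC against adjacent liver these shares were 59%, 4.65% and 12.1%. For all lesions they were 65.3%, 3.9% and 4.68%. For adjacent aged liver against young knockout liver they were 22.8%, 0.2% and 4.96%. For females against males they were 69.8%, 10.6% and 13.6%. False calls were therefore above the set 5% in the 3 comparisons with 1 residual degree of freedom. A simulated list of 25 genes shifted by 0.5 log2 units was detected in all 5 comparisons, and 2 to 4 of 100 unshifted lists had an unadjusted p below 0.05. The simulated genes varied independently and the lists were drawn at random, so this does not test the method on lists of correlated genes.

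The alternatives were halving or doubling the added constant, quantile normalization, and centring each array on its 75th percentile. Others dropped the filter on dim probe sets, raised it to the 65th percentile (a signal of 193.9, 8939 genes), averaged all probe sets of a gene, or counted all probe sets. Further fits had no intensity trend, no pairing term, all 10 arrays together, or left out each array or pair in turn. In the genotype, sex and HCC comparisons, leaving out a young pool or 1 of the 2 HCC pairs left no residual degree of freedom. The model was then fitted to all remaining arrays with group means and sex. Its spread and its sex term come partly from aged tissue, and a lone array is assumed to vary like the other groups. The other comparisons kept their own fit. For adjacent aged against young knockout liver, leaving out a knockout pool or the male adjacent array left 1 array on at least 1 side, because sex is a term. A fit with a clock score per array, and list tests without a doubted array or pair, were added after the values were seen. The arrays had median signals of 77.4 to 102.4, 3' to 5' ratios of 2.46 to 3.62 for Actb and of 0.854 to 1.33 for Gapdh. The number of arrays limits the precision.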

Results

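Liver gene expression was measured in wild-type and Gnmt knockout mice of a mixed 129/B6 strain with 10 Affymetrix arrays of 45101 probe sets each. Gnmt encodes glycine N-methyltransferase, an abundant liver enzyme that consumes S-adenosylmethionine. At 11 weeks there were 2 arrays of wild-type liver and 2 of knockout liver, each a pool of 3 mice of 1 sex. The aged knockout mice gave 6 arrays: a dysplastic nodule and adjacent liver of a 21-month female, an HCC and adjacent liver of an 18-month male, and an HCC and adjacent liver of a 14-month female. Median signals per array ran from 77.4 to 102.4, and the number of arrays limits the precision. Hybridisation controls parted the arrays by age, with BioC to BioB ratios of 2.62 to 3.16 in the 4 young arrays and 0.920 to 1.08 in the 6 aged ones. The 18S 3' probe set was at 115.6 to 292.9 in the young and 19.5 to 79.9 in the aged arrays, and it was lower in each lesion (20.9, 19.5 and 21.5) than in its adjacent liver (79.9, 57.3 and 79.1).

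The knockout could be followed in Gnmt itself, whose signals were 59473 and 52140 in the wild-type pools and 190 and 245 in the knockout pools. The 6 aged knockout arrays had Gnmt signals of 12 to 329. Xist, transcribed from the inactive X chromosome, had signals of 11914 and 7809 in the young female pools and of 33 and 88 in the male pools. The labelled sexes matched these values.

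**Figure D1:**
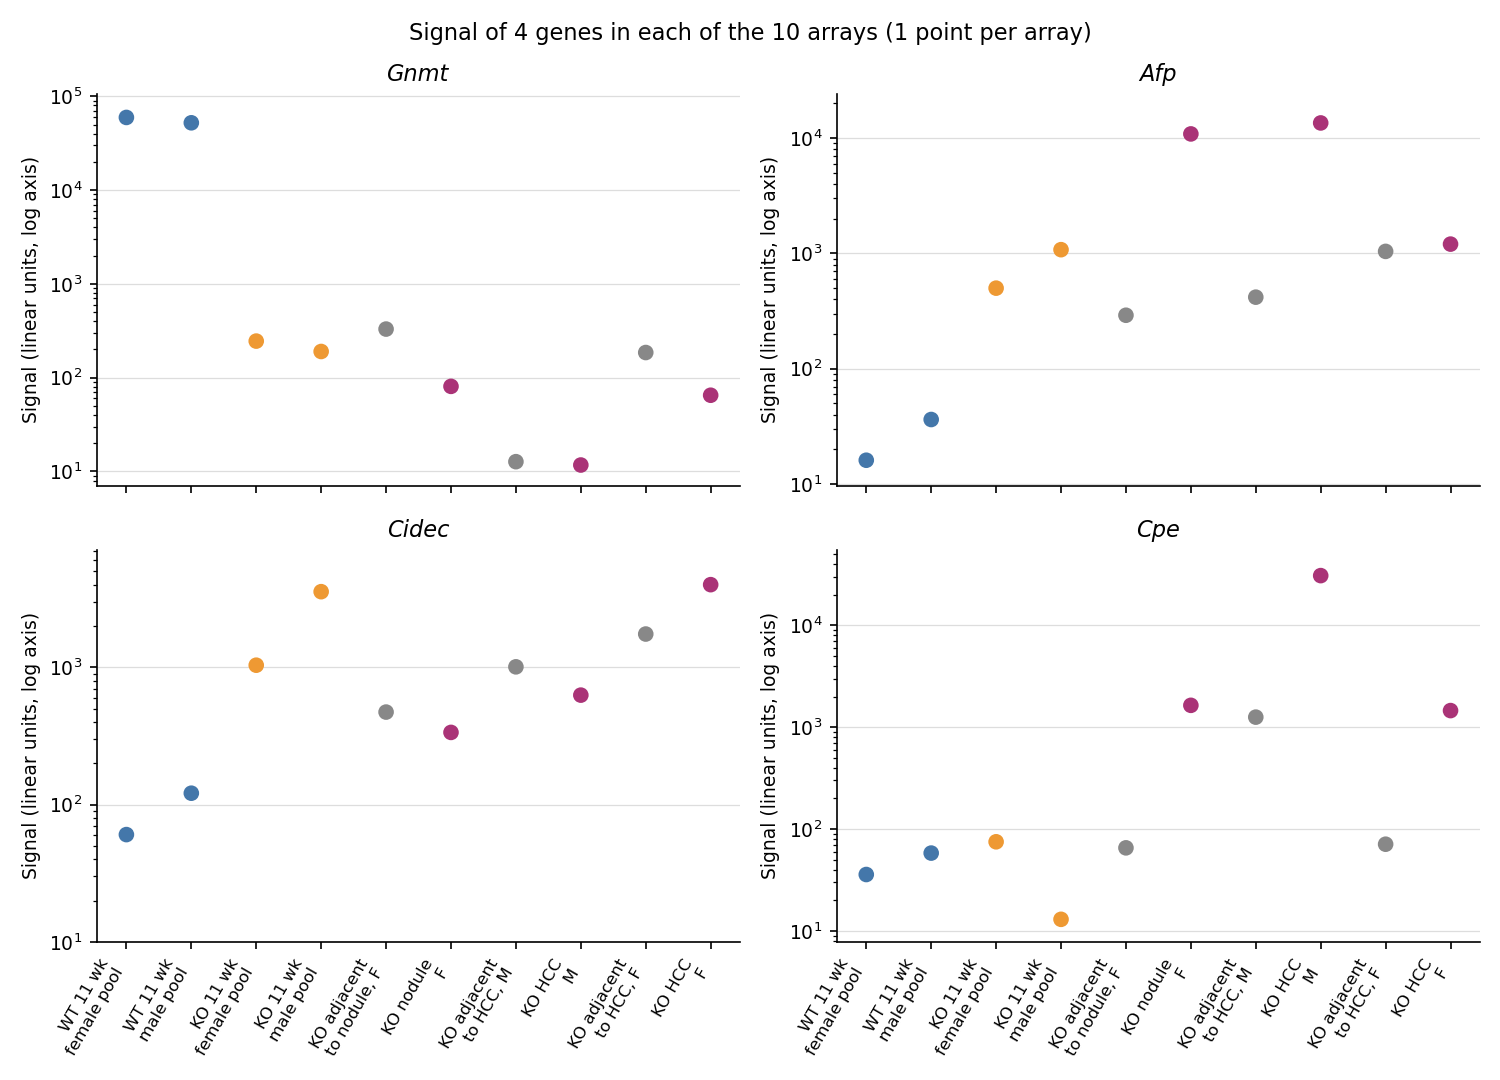
Signal (log axis, arbitrary intensity units) of Gnmt, Afp, Cidec and Cpe in each of the 10 arrays, 1 point per array. Gnmt was at 52140 and 59473 in the wild-type pools and at most 329 elsewhere, and Cpe was higher in each lesion than in its adjacent liver.

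The first comparison asked which liver genes differ without Gnmt at 11 weeks, before tumours. Gnmt fell by 7.90 ± 0.21 (SE, n = 2 pools per genotype, limma adjusted p = 2.13e-05). Cidec, which coats lipid droplets, rose by 4.23 ± 0.30 (adjusted p = 0.00894), from signals of 60 and 121 to 3556 and 1036. Afp, the fetal serum protein alpha-fetoprotein, rose by 4.17 ± 0.37 (adjusted p = 0.0115), from 16 and 36 to 1077 and 500. Ccnd1, the cyclin that drives entry into S phase, rose by 2.92 ± 0.22 (adjusted p = 0.00894). Slco1a1, an organic anion transporter, fell by 3.14 ± 0.44 (adjusted p = 0.0332), and Cyp39a1, an oxysterol hydroxylase, fell by 2.81 ± 0.27 (adjusted p = 0.0139). Cyp39a1 is a chromosomal neighbour of Gnmt, so DNA carried with the targeted locus stays open for it.

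Of 11032 genes, 160 were called, 78 higher and 82 lower in knockout liver, each in the same direction in both sexes. An unadjusted p below 0.05 was reached by 2151 genes, where 552 would be reached by chance. The other large increases were in H2-Bl (3.83), Pls1 (3.60), Mtmr11 (3.59), Tubb2a (3.51), Fabp5 (3.48), Atp6v0e2 (3.34), Ppp1r3g (3.15) and Prss8 (3.12). The other large decreases were in Serpina4-ps1 (-4.24), Sdr9c7 (-3.14), Nox4 (-2.98), Cnmd (-2.90), Enho (-2.71), Ppp1r3c (-2.56) and Cyp2d13 (-2.52). Afp, Pls1, Mtmr11 and Atp6v0e2 each had at least 1 wild-type signal, and Cnmd a knockout signal, below the added constant of 16.8, which sets the size of their differences. The 3' to 5' ratio of Actb, a measure of RNA integrity and labelling, also parted the genotypes, at 2.62 and 2.60 in the wild-type and 3.18 and 3.38 in the knockout pools. That of Gapdh overlapped, at 0.938 and 0.982 in the wild-type and 1.09 and 0.955 in the knockout pools. The test had 1 residual degree of freedom. Leaving out a pool left no residual degree of freedom, so those fits took all other arrays, with the spread and the sex term partly from aged tissue. That model called 1 gene with all 10 arrays, 9 without the wild-type female pool and 0 without any other young pool, so the model and the pool changed together. Without the intensity trend in the variance, 1 gene was called.

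Sterol synthesis genes were higher in both sexes, and genes of fat storage in part. Hmgcs1, which starts the sterol pathway, rose by 1.75 ± 0.19 (adjusted p = 0.0156) and Lss, the lanosterol synthase, by 1.84 ± 0.28 (adjusted p = 0.0399). Sqle differed by 2.14 and did not pass (adjusted p = 0.0694). Of 19 cholesterol synthesis genes, 3 rose and 15 did when adjusted over the list alone, with a median of 1.01. The list passed camera (adjusted p = 5.77e-12), with an adjusted p = 0.852 with an estimated correlation. Of 26 fatty acid synthesis and lipid storage genes, Cidec and Mogat1 (2.80) rose, and over the list alone 5 rose and 2 fell. Their median was 0.61, but 1.14 in females and -0.01 in males, an untested difference. That list passed at an adjusted p = 0.000831, and had an adjusted p = 0.852 with an estimated correlation. Without the wild-type female pool, in the model over all remaining arrays, it did not pass (median 0.00843, adjusted p = 0.921).

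Glucose, bile acid and drug metabolism genes were lower in part. G6pc, the last enzyme of glucose release, fell by 1.82 ± 0.19 (adjusted p = 0.0147), and the glycogen-targeting subunits Ppp1r3c and Ppp1r3b (-1.38) fell while Ppp1r3g rose. Of 20 gluconeogenesis and glycogen genes, 1 rose and 3 fell (2 and 7 adjusted over the list alone; median -0.33). In bile acid metabolism, Slco1a1 and Cyp8b1 (-1.44), the sterol 12-alpha-hydroxylase, fell among 20 genes, 8 when adjusted over the list alone, with a median of -0.39. Cyp8b1 differed by -1.66 in females and -1.23 in males, and it was positive only in fits over all arrays that left out 1 pool and drew the sex term partly from aged tissue. Of 17 targets of the drug receptors CAR and PXR, Sult1e1 (3.12) rose and 4 fell, with 1 and 6 adjusted over the list alone. Those that fell included Cyp2c54 (-2.35), Cyp2c37 (-2.17) and Cyp2b10 (-1.92), whose probe sets may be shared with relatives. The 3 lists passed camera at adjusted p of 0.0199, 0.000181 and 0.0146. Gluconeogenesis had an adjusted p = 0.878 with an estimated correlation, and the other two had an adjusted p = 0.852 with an estimated correlation. CAR and PXR targets had medians of -0.24 in females and -0.42 in males, and did not pass in the model over all remaining arrays without the wild-type female pool (-0.28, adjusted p = 0.0808).

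Genes of cell division and of the fetal liver were higher. Cdc20, an activator of mitotic exit, rose by 1.89 ± 0.32 (adjusted p = 0.0464), while Cdk1 (2.06) and Ccnb2 (2.51) did not pass. Of 22 cell cycle genes 1 rose, 3 when adjusted over the list alone, with a median of 1.03 and 20 of 22 positive. Of 21 fetal liver and liver tumour markers, Afp, Ly6d (2.71), Bex4 (2.50) and Lpl (2.09) rose and 1 fell, with 8 and 1 adjusted over the list alone and a median of 0.64. Both lists passed camera, at adjusted p of 1.13e-05 and 0.000814, and had an adjusted p = 0.852 with an estimated correlation. Of 20 beta-catenin pathway genes, Ccnd1 rose and Notum (-1.64) fell, the same when adjusted over the list alone, with a median of -0.48. Of 17 p53 targets 0 were called in limma over all genes and 4 rose when adjusted over the list alone, with a median of 0.53. The beta-catenin and p53 lists passed at adjusted p of 0.0116 and 0.012, and had an adjusted p = 0.852 with an estimated correlation and an adjusted p = 0.878 with an estimated correlation.

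Endothelial and male-biased genes were lower, and macrophage genes as a list only. Stab2 (-1.55), a scavenger receptor of sinusoidal endothelium, and Oit3 (-1.35) fell among 17 endothelial genes, 8 when adjusted over the list alone, with a median of -0.84 and 16 negative. Of 15 male-biased liver genes, Slco1a1, Nox4 and Elovl3 (-1.93) fell, 6 when adjusted over the list alone, with a median of -0.72. Both lists passed camera, at adjusted p of 2.66e-06 and 0.000135, and had an adjusted p = 0.852 with an estimated correlation. Of 18 macrophage and Kupffer cell genes 0 were called, also over the list alone, with a median of -0.56, Cybb at -0.96 and Slc40a1 at -0.86. That list passed at an adjusted p = 0.000682 and had an adjusted p = 0.913 with an estimated correlation. Its medians were -0.89 in females and -0.28 in males, an untested difference, and it did not pass without the wild-type female pool in the model over all remaining arrays (-0.25, adjusted p = 0.298). There the endothelial median was -0.45 (adjusted p = 0.0197) and the male-biased median -1.36 (adjusted p = 1.56e-06).

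The enzymes around Gnmt did not shift as a group. Among 26 methionine and one-carbon genes 0 were called by limma, also over the list alone, with a median of 0.06 (camera adjusted p = 0.845), Nnmt at 1.17 and Cdo1 at -0.71. DNA methylation genes (9, median 0.03) did not pass. Nor did RAS and JAK-STAT inhibitors (-0.18), fatty acid oxidation (0.08), NRF2 targets (0.22), interferon response (-0.14), hepatocyte function (-0.12) or unfolded protein response (-0.09). Within these lists Acot2 (1.44), Pgd (2.08) and Asns (1.86) rose and Gclc (-1.37) fell. Acute phase genes (0.13), with Orm2 (2.42) higher and Saa4 (-2.33) lower, did not pass, nor did the stellate (0.11), cholangiocyte (-0.32), neutrophil (-0.17), and B and plasma cell (0.03) lists. Of 15 female-biased genes 3 rose and 0 fell, with 4 and 4 when adjusted over the list alone. These genes had a median of -0.33, a mean of 0.14 and an upward test that did not pass (camera adjusted p = 0.956). Their median was -0.17 in the male pools, but 0.88 without the wild-type female pool in the model over all remaining arrays. Extracellular matrix genes had a median of -0.06, a mean of 0.16 and Lgals1 higher by 2.75. Without the wild-type female pool, in the model over all remaining arrays, acute phase (0.58, adjusted p = 2.38e-08), matrix (0.43, 0.00452) and neutrophil genes (0.73, 0.0427) passed. That model draws its sex term partly from aged tissue, and the male pools alone had medians of 0.19, 0.09 and -0.05. With fry, 0 of 27 lists passed for a shift one way, with a lowest adjusted p of 0.499. For change in either direction 1 passed, gluconeogenesis and glycogen (fry adjusted p = 0.00745).

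**Figure D2:**
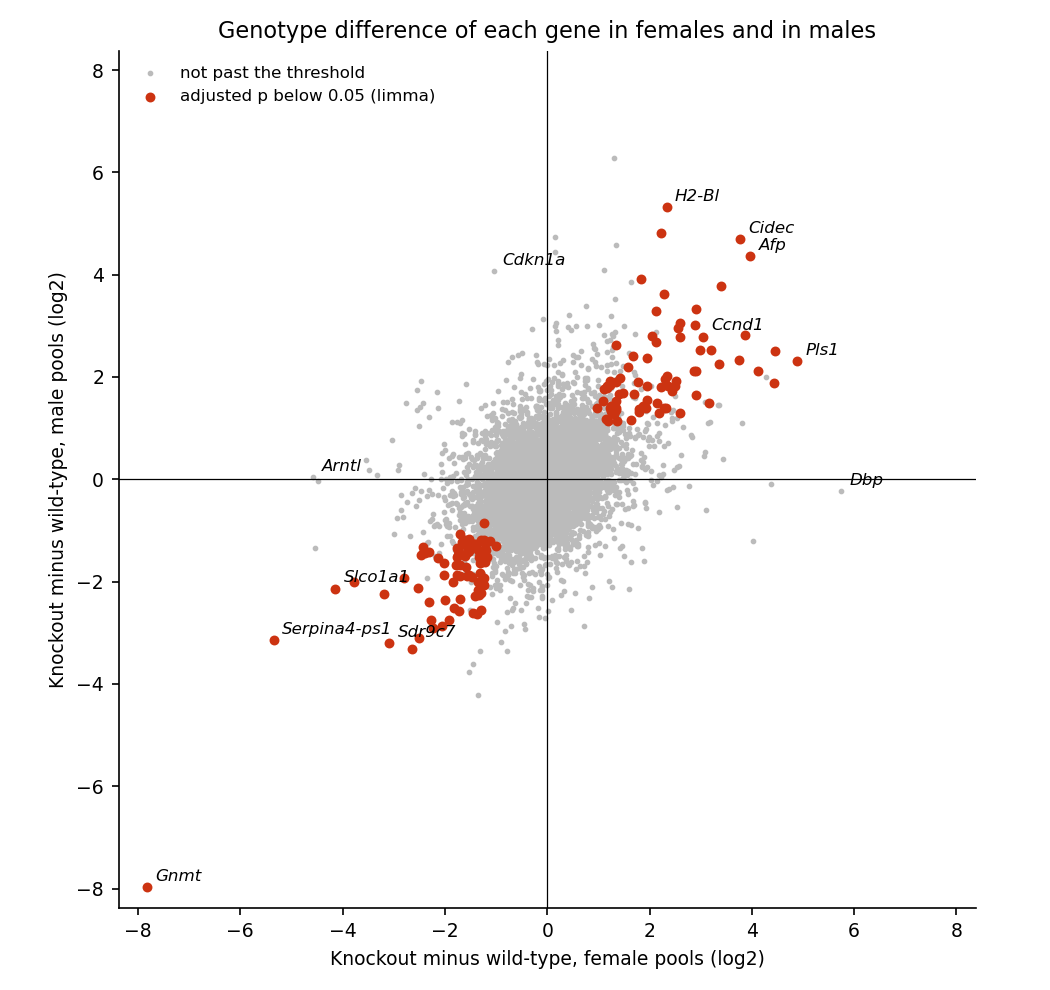
Knockout minus wild-type difference (log2) of each of 11032 genes in the female pools (horizontal) and the male pools (vertical), with the 160 called genes in red. The correlation across genes was 0.435, and the called genes lay in the quadrants where both sexes had the same sign.

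The genotype difference of females and of males had a Pearson correlation of 0.435 and a Spearman correlation of 0.413 across genes, which are not independent replicates. At least 2-fold differences were found for 1244 genes in females and 1390 in males, of which 391 went the same way in both sexes (197 higher, 194 lower) and 41 the opposite way. This was 1 of 5 such correlations computed.

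**Figure D3:**
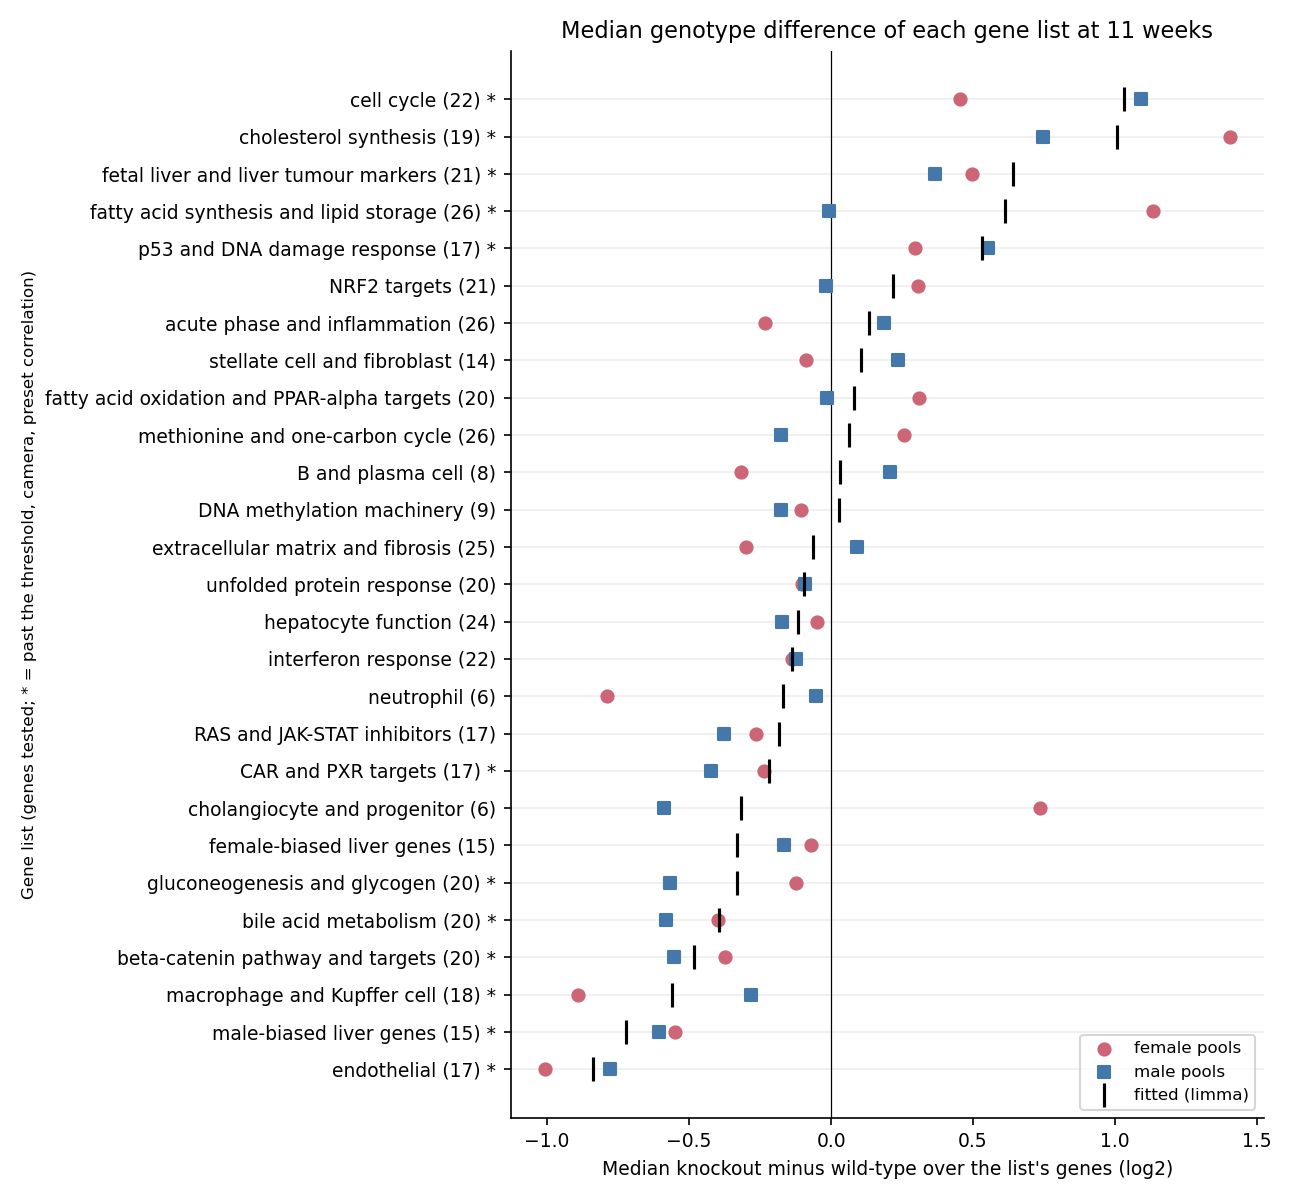
Median knockout minus wild-type difference (log2) of each gene list in the female pools, the male pools and the fit, with an asterisk for lists past the camera threshold. Cholesterol synthesis was at 1.40 in females and 0.75 in males, and fatty acid synthesis at 1.14 and -0.01.

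Several genes of the circadian clock set the wild-type female pool and the male HCC mouse apart from most other arrays. Arntl, a clock activator, had a signal of 911.5 in the wild-type female pool and of 22.2 to 85.2 in the other 3 young pools. Dbp, its target, had a signal of 190.6 there and of 8414 to 11097 in the others. In the male HCC mouse, Arntl was at 847.2 in the tumour and 553.2 in adjacent liver, and Dbp at 42.2 and 213.6. Per3 followed Dbp, at 75.2 in the wild-type female pool and 294.7 to 424.4 in the other young pools. Nr1d1, at 590.3, did not stand apart there, nor did Cry1, at 344.2 against 352.1 in the wild-type male pool. In the female HCC mouse Arntl was in between, at 382 in the tumour and 337.7 in adjacent liver.

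**Figure D4:**
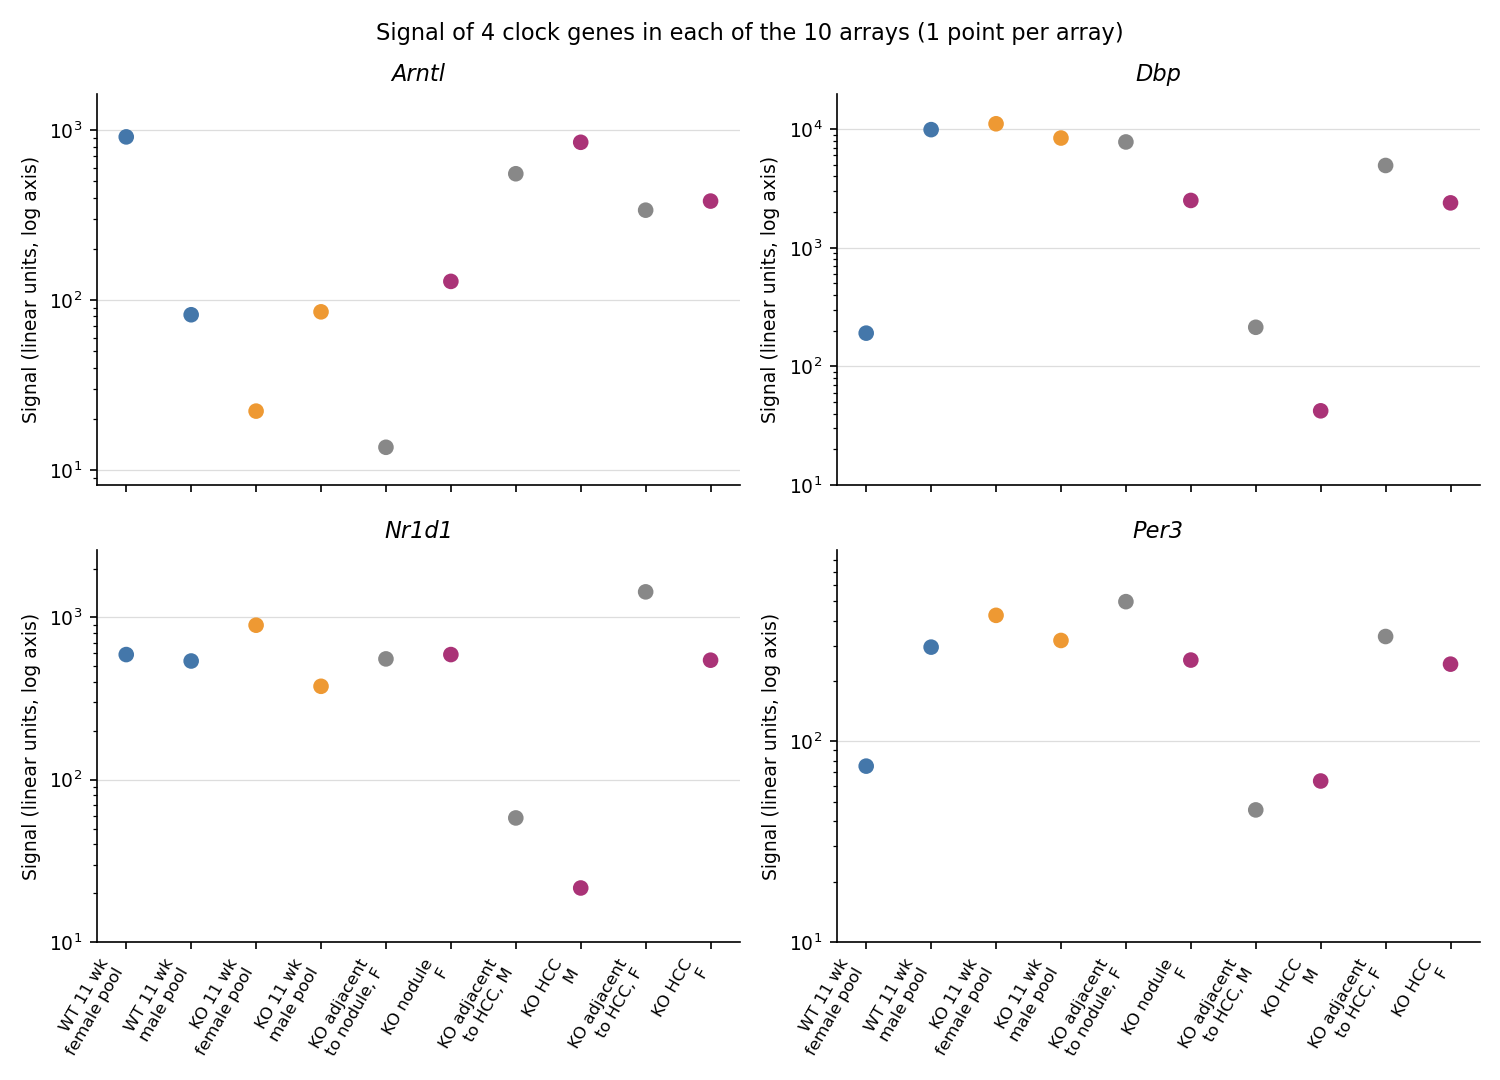
Signal (log axis, arbitrary intensity units) of the clock genes Arntl, Dbp, Nr1d1 and Per3 in each array, 1 point per array. Dbp was at 190.6 in the wild-type female pool and at 42.2 and 213.6 in the male HCC mouse, against at least 2390 in the other 7 arrays.

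The next comparison asked how females differ from males at 11 weeks, across both genotypes. Sult3a1, a female-biased sulfotransferase, was higher in females by 10.19 ± 0.24 (SE, n = 2 pools per sex, limma adjusted p = 8.82e-06). Xist was higher by 7.06 ± 0.39 (adjusted p = 0.00122), and Sult2a2 by 7.22 ± 0.37 (adjusted p = 0.00122). Eif2s3y, on the Y chromosome, was lower in females by -5.04 ± 0.32 (adjusted p = 0.00187), and Elovl3, a fatty acid elongase, by -3.23 ± 0.23 (adjusted p = 0.00247). Signals below the added constant of 16.8 set the size of some of these differences, as for Sult3a1 (5.4 and 3.0 in males), Cyp2b9 (7.7 in the knockout male pool), Cyp2b13, Slc22a29 and Eci3 (5.2, 4.0 and 14.7 in the wild-type male pool) and Scara5 (16.2 and 4.1 in females). In all, 30 genes were called, 18 higher and 12 lower, and 1016 had an unadjusted p below 0.05. Others higher in females were Cyp2b9 (6.96), Cyp2b13 (6.17), Slc22a26 (4.71), Slc22a29 (4.27), Eci3 (3.81), Acnat2 (3.68) and Slc22a27 (3.63). Others lower were Scara5 (-5.85), Cyp4a12a (-4.08), Obp2a (-4.01), Serpina12 (-3.07), Ugt2b38 (-2.95), Alas2 (-2.93), C6 (-2.92) and Cyp7b1 (-2.72). Acnat2 differed by 4.38 in wild-type and 2.98 in knockout liver, and Cyp4a12a by -5.17 and -2.99. Leaving out a pool required the model over all arrays, in which the sex difference also includes aged tissue. It called 8 genes with all 10 arrays, 21 and 22 without the wild-type female and male pool, and 5 without either knockout pool.

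The sex lists followed these genes. Of 15 male-biased genes 6 fell in females, 12 when adjusted over the list alone, with a median of -1.60 (camera adjusted p = 4.18e-19). Of 15 female-biased genes 6 rose, 10 when adjusted over the list alone, with a median of 1.58 (adjusted p = 1.48e-17). CAR and PXR targets (0.35, adjusted p = 0.000116), with 2 of 17 higher and 7 when adjusted over the list alone, and cell cycle genes (-0.64, adjusted p = 4.45e-06) also passed. These 4 lists had an adjusted p = 0.914 with an estimated correlation. Beta-catenin genes (0.43, adjusted p = 0.000144) passed, with an adjusted p = 0.979 with an estimated correlation. Hepatocyte (0.16, adjusted p = 0.00605) and stellate cell genes (0.41, adjusted p = 0.0368) passed, with an adjusted p = 1 with an estimated correlation. With fry 0 lists passed for a shift one way (lowest adjusted p 0.243), and 1 for change in either direction, CAR and PXR targets (fry adjusted p = 0.0408). The sex differences of the 2 genotypes had a Pearson correlation of 0.278 and a Spearman correlation of 0.192 across genes, which are not independent replicates, and 147 genes were at least 2-fold different the same way and 41 the opposite way.

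The comparison of HCC with adjacent liver asked which genes mark the tumours. Cpe, carboxypeptidase E, which trims prohormones, rose by 4.33 ± 0.28 (SE, n = 2 pairs, limma adjusted p = 0.00149), with signals of 30750 against 1255 in the male and 1455 against 71 in the female. Pfkp, a phosphofructokinase of glycolysis, rose by 3.11 ± 0.29 (adjusted p = 0.0152). Itga6, a laminin receptor, rose by 3.00 ± 0.35 (adjusted p = 0.0342), and Slpi, a secreted protease inhibitor, by 2.60 ± 0.26 (adjusted p = 0.0196). Slco1a4, a bile acid and drug transporter, fell by 2.18 ± 0.27 (adjusted p = 0.0399).

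In all, 9 genes were called, 7 higher and 2 lower, and 844 had an unadjusted p below 0.05. The others were Pnpla3 (3.43), Tspan8 (2.73), Mfge8 (2.44) and Obp2a (-2.52). Lower values that did not pass were those of Lrtm2 (-2.46), Scnn1a (-2.23), Mmd2 (-2.19), Atoh8 (-2.02), Slc22a15 (-1.97), Cyp7b1 (-1.94), Gsta2 (-1.93) and Numbl (-1.90). The test had 1 residual degree of freedom. With either pair left out, the difference was that of 1 HCC and 1 adjacent array, assumed to vary like the other groups in a model over all remaining arrays. That model called 0 genes with all 10 arrays, 9 without the male pair and 5 without the female pair, which does not measure the stability of the 9 calls. The HCC differences of the male and the female had a Pearson correlation of 0.117 and a Spearman correlation of 0.103 across genes, which are not independent replicates. At least 2-fold differences were found for 1009 genes in the male and 1136 in the female, with 166 the same way (100 higher, 66 lower) and 91 the opposite way.

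Lipid, tumour marker, division and matrix genes were higher in HCC. Among 26 fatty acid synthesis and lipid storage genes Pnpla3 rose, 5 when adjusted over the list alone, with a median of 0.63 and 26 of 26 positive. Fetal liver and tumour markers had a median of 1.46, with 10 rising and 1 falling when adjusted over the list alone, and 0 called by limma over all genes. Of those markers, Afp was at 13519 against 417 in the male and 1204 against 1041 in the female, and Igf2 differed by 5.70 and 0.15. Cell cycle genes had a median of 1.01 and 7 rose when adjusted over the list alone, with Mki67 at 1.92 not passing over all genes. Matrix genes had a median of 0.71 and 2 rose when adjusted over the list alone, with Sparc at 1.79 not passing. In the order of the male and female pair, the medians were 0.26 and 1.14 for lipid, 1.64 and 0.21 for fetal marker, 1.24 and 0.42 for cell cycle and 0.23 and 1.01 for matrix genes, untested differences. The 4 lists passed camera at adjusted p of 4.6e-11, 6.1e-09, 1.52e-08 and 3.35e-08, and each had an adjusted p = 0.582 with an estimated correlation.

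Genes of drug, bile acid and methyl metabolism were lower in HCC. CAR and PXR targets had a median of -0.78, with Cyp2c50 (-1.70), Cyp2c37 (-1.62) and Cyp2c54 (-1.52) not passing and 8 of 17 falling when adjusted over the list alone. Bile acid genes had a median of -0.64, where Slco1a4 fell, and 4 fell when adjusted over the list alone. Of 26 methionine and one-carbon genes 22 were negative, with a median of -0.36, 3 falling when adjusted over the list alone, and Mat1a, which makes S-adenosylmethionine, at -1.37 not passing. Beta-catenin genes had a median of -0.50, with Oat (-1.87) and Cyp1a2 (-1.56) not passing and 4 falling when adjusted over the list alone. These lists passed camera at adjusted p of 3.4e-07, 8.57e-07, 1.67e-06 and 5.69e-06, and each had an adjusted p = 0.582 with an estimated correlation.

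Other lists that passed camera in HCC were male-biased genes (-0.54, adjusted p = 0.000306), endothelial genes (0.26, 0.000787, 17 of 17 positive), cholangiocyte genes (0.25, 0.0226), NRF2 targets (-0.37, 0.028) and RAS and JAK-STAT inhibitors (0.21, 0.029). These had an adjusted p = 0.582 with an estimated correlation. In the order of the male and female pair, the medians were -0.97 and -0.05 for male-biased, 0.42 and 0.18 for endothelial and 0.05 and 1.24 for cholangiocyte genes. They were -0.33 and -0.06 for NRF2 targets and 0.50 and 0.14 for RAS and JAK-STAT inhibitors, and none of these differences was tested. Unfolded protein response (0.24, adjusted p = 0.00591) and interferon genes (0.20, 0.0122) passed, with an adjusted p = 0.629 with an estimated correlation. Hepatocyte genes passed at a median of -0.07 (adjusted p = 0.029), with an adjusted p = 0.775 with an estimated correlation. The other 11 lists did not pass, among them cholesterol synthesis (adjusted p = 0.989) and acute phase genes (adjusted p = 0.187). With fry 0 of 27 lists passed, with a lowest adjusted p of 0.469.

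The nodule and the HCCs together were set against adjacent liver to ask what all 3 lesions share. Cpe rose by 4.33 ± 0.20 (SE, n = 3 pairs, limma adjusted p = 0.00272), by 4.60 and 4.07 in the HCC pairs and 4.33 in the nodule, where signals were 1639 and 65. It was the only gene called, and 1096 genes had an unadjusted p below 0.05. Values that did not pass were those of Tspan8 (2.71 ± 0.22, adjusted p = 0.0529), Mfge8 (2.73), Itga6 (2.74), Spink1 (3.87), Cdkn2b (3.10), Aldh18a1 (2.96), Elapor1 (2.78), Nucb2 (2.68) and Esm1 (2.63). Lower values that did not pass were those of Slco1a4 (-2.07 ± 0.19, adjusted p = 0.0691), Obp2a (-2.23), Atoh8 (-2.10), Oat (-2.04), Hamp2 (-1.97), Cyp2c37 (-1.76), Cyp2c50 (-1.62), Neb (-1.62), Cyp2c23 (-1.59) and Dbp (-1.55). Without the male HCC pair 177 genes were called (122 higher, 55 lower), without the nodule pair 9 and without the female HCC pair 2, and Cpe was in each set.

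Matrix and cell cycle genes were again higher across the 3 pairs. Matrix genes had a median of 0.84 (camera adjusted p = 3.8e-10), an adjusted p = 0.351 with an estimated correlation, and 14 of 25 rose when adjusted over the list alone. Cell cycle genes (1.03, adjusted p = 2.33e-09), with 10 of 22 higher over the list alone, had an adjusted p = 0.28 with an estimated correlation. Col1a1 (2.32), Col3a1 (1.49), Aurka (2.08) and Cdk1 (1.93) did not pass over all genes. Fetal markers (1.42, 1.49e-06), endothelial genes (0.34, 4.16e-05), bile acid (-0.49, 1.79e-06), methionine (-0.33, 2.09e-06), CAR and PXR (-0.52, 5.05e-05) and beta-catenin genes (-0.57, 5.58e-05) passed. Each of these 6 had an adjusted p = 0.28 with an estimated correlation. Without the male HCC pair the medians of matrix and fetal marker genes were 1.28 and 0.48, and both lists passed.

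Another 10 lists passed over the 3 pairs. Cholesterol synthesis genes (-0.69, adjusted p = 8.65e-06) had medians of 0.48 and -0.34 in the male and female HCC and of -2.04 in the nodule, and an adjusted p = 0.512 with an estimated correlation. NRF2 targets (0.39, 0.00429) had medians of -0.33, -0.06 and 1.5, and fatty acid synthesis genes (0.29, 0.0128) of 0.26, 1.14 and -0.61. These had an adjusted p = 0.592 with an estimated correlation. Hepatocyte (-0.20, 0.00122), interferon (0.37, 0.00145), unfolded protein response (0.33, 0.00145), macrophage (0.39, 0.00152), male-biased (-0.56, 0.0103), RAS and JAK-STAT (0.38, 0.0166) and fatty acid oxidation genes (-0.19, 0.0166) passed, at the lowest with an adjusted p = 0.351 with an estimated correlation. Without the male HCC pair, RAS and JAK-STAT (adjusted p = 0.161), fatty acid oxidation (0.118), male-biased (0.419) and unfolded protein response genes (0.13) did not pass. Without that pair, gluconeogenesis (0.00417), female-biased (8.65e-05) and cholangiocyte genes (0.025) passed. The medians of cholesterol synthesis (-1.21), NRF2 (0.67), hepatocyte (-0.44) and interferon genes (0.57) were then larger in size. With fry 0 lists passed for a shift one way (lowest adjusted p 0.15), and 10 for change in either direction.

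**Figure D5:**
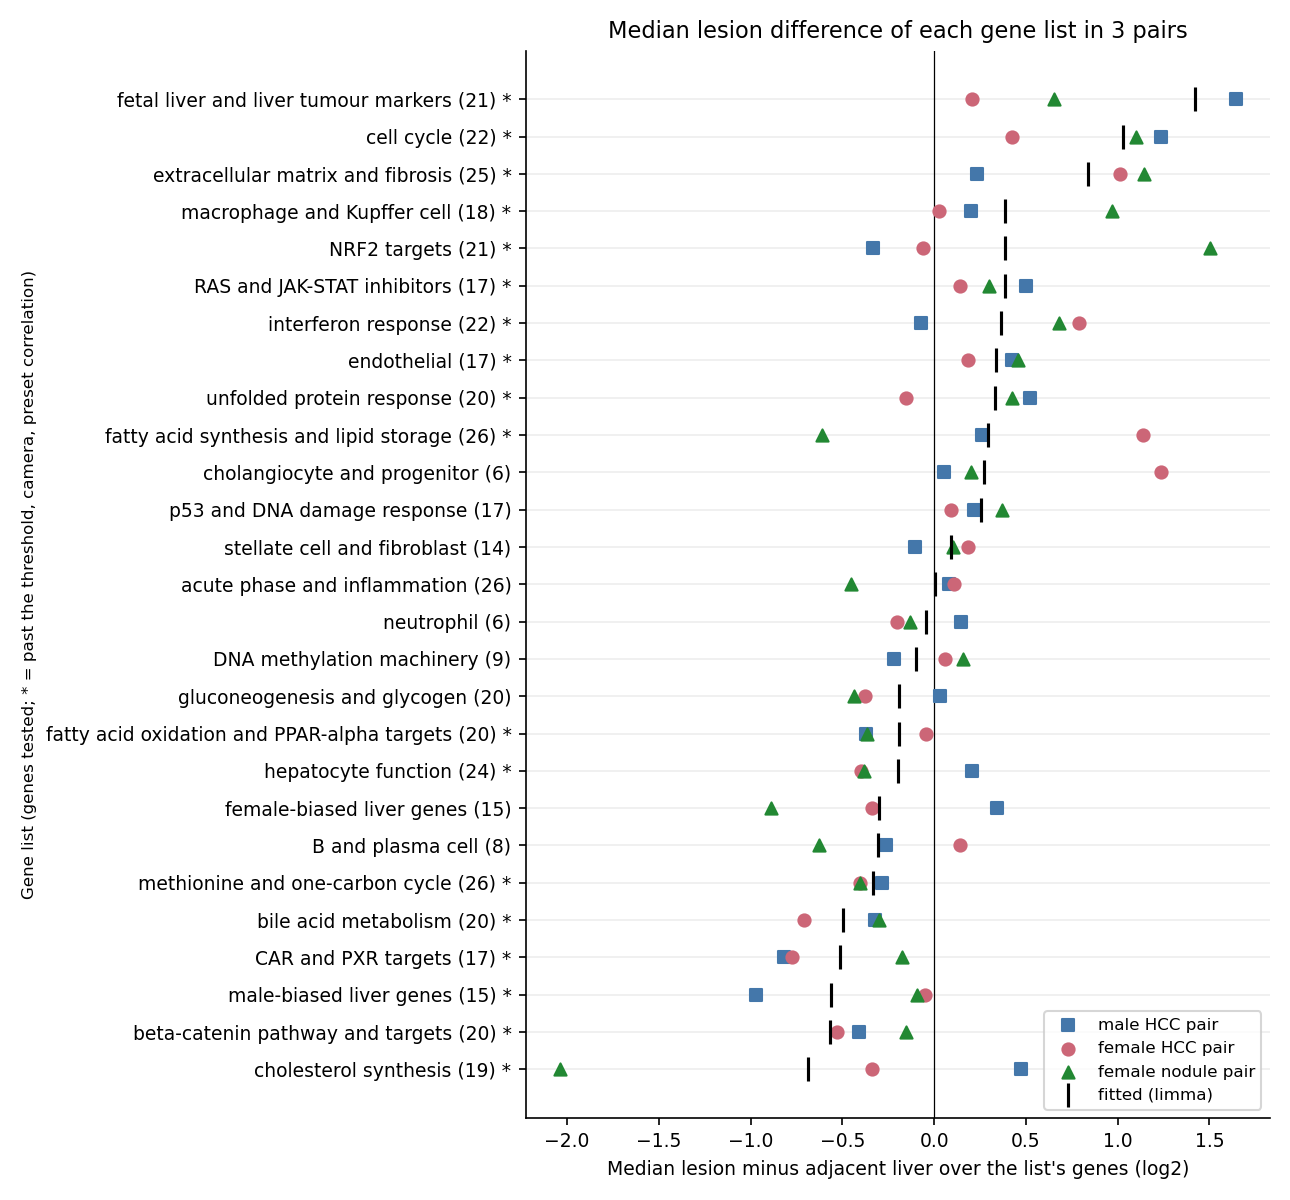
Median lesion minus adjacent difference (log2) of each gene list in the male HCC pair, the female HCC pair and the nodule pair, with the fitted value as a tick. NRF2 targets were at 1.5 in the nodule and -0.33 and -0.06 in the HCCs, and cholesterol synthesis at -2.04, 0.48 and -0.34.

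The dysplastic nodule was also set against its adjacent liver alone, with 1 array a side and no test. Cbr3, a carbonyl reductase, had signals of 22685 and 309, Abcc4, an efflux pump, 21089 and 456, and Gclc, which limits glutathione synthesis, 33594 and 2214. Of 21 NRF2 targets 19 were at least 2-fold higher, with a median of 1.5 at the 100th percentile of 10000 random lists. Of 19 cholesterol synthesis genes 18 were at least 2-fold lower, with a median of -2.04 at the 0th percentile, with Pmvk at -2.50 and Tm7sf2 at -2.45. The matrix (1.14), cell cycle (1.10), macrophage (0.97) and interferon medians (0.68) were also at the 100th percentile, and those of female-biased (-0.89) and fatty acid synthesis genes (-0.61) at the 0th.

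In the nodule 862 genes were at least 2-fold higher and 426 lower. The largest differences were those of Heph (6.69), Slc22a12 (6.41), Cyp4a12a (6.16), Cbr3 (6.12), Gpx2 (6.02), Abcc4 (5.48), Ubd (5.46), Afp (5.14), Spink1 (4.82) and Elovl7 (4.60). Afp was at 2.52 when its probe sets were averaged. The most negative were Fmr1nb (-4.59), Syde2 (-3.41), Tcl1b3 (-3.16), Vipr1 (-3.0), Eci3 (-2.70), Cyp8b1 (-2.63), Mup10 (-2.55), Mfsd2a (-2.55), Ngp (-2.54) and Pmvk (-2.50). Heph, at 4.0 in adjacent liver, and Fmr1nb and Ngp, at 9.0 and 15.9 in the nodule, had signals below the added constant of 16.8, which sets the size and rank of their differences. Syde2 (18.6 in the nodule), Vipr1 (30.4), Slc22a12 (32.7 in adjacent liver), Spink1 (36.2) and Gpx2 (38.6) were close to it. Across genes, which are not independent replicates, the nodule difference had a Pearson correlation of 0.285 with the female HCC and 0.104 with the male HCC, and Spearman correlations of 0.265 and 0.0836. It shared 296 genes at least 2-fold the same way with the female HCC and 183 with the male HCC, with 76 and 105 opposite.

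The last comparison asked how lesion-adjacent liver of aged knockout mice differs from knockout liver at 11 weeks. No gene was called by limma: 0 passed, 1355 had an unadjusted p below 0.05, and the lowest adjusted p was 0.292. Values that did not pass were higher for immunoglobulin genes, Igkv8-30 (3.52 ± 0.44, SE, n = 3 against 2 arrays), Ighm (3.36), Igha (2.71) and Iglv1 (2.70), whose probe sets may be shared. The B and plasma cell list did not pass, with a median of 0.47, 6 of 8 positive and a camera adjusted p of 0.0759. Other higher values that did not pass were those of Siglece (3.08), Sftpd (3.05), Cxcl1 (2.99), Cxcl13 (2.85), Tinag (2.63) and Tmprss4 (2.59). Lower values that did not pass were those of Sult2a8 (-4.13 ± 0.58), Cyp8b1 (-3.63), G0s2 (-2.44), Akr1c19 (-2.11), Akr1c18 (-2.02), Acot1 (-1.95) and Lifr (-1.30). Fits without the nodule-adjacent array called 110 genes, and without the female HCC-adjacent array 9. Without the knockout female pool, sex as a term left only the male HCC-adjacent array against the male knockout pool. The count of that fit says nothing about stability. Age, the presence of a lesion, the hybridisation controls and the 18S 3' probe set all separate these groups, and cannot be told apart.

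Fat oxidation genes were lower and inflammation genes higher in the aged liver as lists. Of 20 fatty acid oxidation and PPAR-alpha targets 19 were negative, with a median of -0.67 (camera adjusted p = 1.45e-10), 8 falling when adjusted over the list alone, Cyp4a14 at -1.73 and Ehhadh at -1.35. All 26 acute phase genes were positive, with a median of 0.77 (adjusted p = 4.31e-08), and 3 rose when adjusted over the list alone. Neutrophil genes were positive in 6 of 6, with a median of 1.41 (adjusted p = 0.000518), 3 rising when adjusted over the list alone, S100a8 at 2.94 and S100a9 at 2.88. These 3 lists had an adjusted p = 0.605 with an estimated correlation. Without the male HCC-adjacent array their medians were -0.38, 0.33 and 0.57. With sex as a term, that fit set the female adjacent livers against the female knockout pool alone, so the young baseline changed too. S100a8 had signals of 8788 and 10076 in the tumour and adjacent liver of the male HCC mouse and of 88 to 700 in the other arrays, and Cd14 of 23675 and 28786 against 151 to 1559. The acute phase median against young knockout was 1.59 in that mouse's adjacent liver, 0.06 in the female HCC-adjacent liver and 0.29 in the nodule-adjacent liver.

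The other lists that passed were bile acid (-0.57, adjusted p = 0.000488), macrophage (0.69, 0.00108), male-biased (-0.58, 0.00338), female-biased (-0.81, 0.00362), fatty acid synthesis (-0.32, 0.00721), methionine (-0.16, 0.00721), gluconeogenesis (-0.11, 0.0217) and DNA methylation genes (0.50, 0.0272, 9 of 9 positive, Dnmt1 at 1.01). Each had an adjusted p = 0.605 with an estimated correlation. Matrix genes (0.39, adjusted p = 0.0068) passed, with an adjusted p = 0.745 with an estimated correlation. Without the male HCC-adjacent array, where the female knockout pool alone was the baseline, bile acid genes were at -0.36, male-biased genes at -0.39 and matrix genes at -0.12. In that fit cholesterol synthesis genes were at 0.44, hepatocyte genes at -0.20 and p53 genes at 0.46. With fry 0 lists passed, with a lowest adjusted p of 0.447.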

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

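The tests of the male HCC mouse's clock, of female differences in males, of the fatty acid list and of the acute phase list were chosen only after the result was seen.

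Clock genes were out of step in the wild-type female pool, with Arntl at 911.5 and Dbp at 190.6, and in both tissues of the male HCC mouse. The female HCC mouse, counted below among the other 4 aged arrays, lay in between for Arntl, at 382 and 337.7. The median of 5 other clock genes of the Dbp phase, set aside before being looked at, was also compared. It was lower in the wild-type female pool by 0.60 log2 units than in the lowest other young pool, past the bound of 0.5 set for the test. The medians were -0.99 in the wild-type female, -0.39 in the knockout female, -0.16 in the knockout male and 0.71 in the wild-type male pool. The other young pools thus lay further apart than 0.60, so the gap does not decide on another time of day at collection. Wee1, Tspan4 and Bhlhe40 were lowest in that pool among the 4 young pools, while Lonrf3 and Tsc22d3 were highest there. In the male HCC mouse the same 5 genes differed by 0.20 (the other 4 aged arrays minus that mouse), between the bounds of 0.1 and 0.5 set for the test, which does not decide. Inflammation in that mouse and time of day cannot be told apart for its clock genes.

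Time of day as the whole of the genotype difference was set against the males. Their 2 pools were alike in the clock genes first seen, with Arntl phase minus Dbp phase medians of -1.75 in wild-type and -1.68 in knockout. The 1243 genes at least 2-fold different in females, Gnmt left out, had a median male effect of 0.58 in the female direction (quartiles 0.10 and 1.19), 975 with the same sign. The clock genes set aside had medians of 0.71 in the wild-type and -0.16 in the knockout male pool, so these pools may not have been in step. The male effect therefore argues against time of day only as far as the clock genes first seen show. The fatty acid synthesis and lipid storage list had a median of 1.14 in females and -0.0082 in males, a male minus female difference of -1.14 that was not tested. Wild-type females were at -0.30 against wild-type males, and knockout females at 0.55 against knockout males. The time of day or feeding state of the wild-type female pool and an effect of Gnmt that depends on sex cannot be told apart for this list.

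The genes called between genotypes could include genes carried with the targeted locus, since the mice are of mixed 129 and B6 origin. Of the 200 tested genes nearest to Gnmt on chromosome 17, 3 were called (H2-Bl, Cyp39a1 and Rcan2), 1.5% against 1.44% of the 10799 others (one-sided Fisher exact p = 0.555). None of the nearest 40 was called: 0 by limma. The test argues against 129 DNA around the locus as a source of most calls. It leaves this open for the 3 called neighbours, which all lay on the same side of Gnmt. Among the tested genes Cyp39a1 and Rcan2 were next to each other, and H2-Bl lies in the variable histocompatibility region. Rcan2 (2.18 ± 0.23, SE, n = 2 pools per genotype) is named because it was a neighbour, after its value was seen.

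Acute phase genes were higher in lesion-adjacent aged liver than in young knockout liver. The 3 adjacent arrays, alike in their hybridisation controls, differed among themselves by 1.53 log2 units in the list median, which argues against the hybridisation batch as the whole cause. The male HCC-adjacent array had the highest median, and without that mouse the list median was 0.33 rather than 0.77. With sex as a term, the young male knockout pool then no longer counted in the difference, so both groups changed at once. Inflammation in that mouse alone and a lesser shift in aged livers generally cannot be told apart with 2 other arrays. Age, lesion and batch stay open for the remaining shift, and no biological explanation was tested.

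The single gene called across all lesions, Cpe, was set against regroupings of the 6 arrays. The real grouping called 1 gene, and the highest of the other groupings called 0. With 10 groupings, 4 of which part every pair, no share below 0.1 can be reached. Only the real grouping itself, 1 of 10, called a gene, so the test does not decide.

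Several genes and lists had opposite signs in the 2 pairs of a comparison, and none of these differences was tested. Cdkn1a, the p21 cell cycle inhibitor, had a genotype difference of 4.07 in males and -1.04 in females, 5.11 apart. The same gene had sex differences of -1.87 in knockout and 3.24 in wild-type liver. Their difference of -5.11 restates the same contrast of the same pools and is not a further observation. S100a9 had sex differences of -2.37 in knockout and 1.10 in wild-type liver, a difference of -3.47. Thrsp, a lipogenic regulator, had sex differences of 1.20 in knockout and -4.04 in wild-type liver, 5.24 apart. Between HCC and adjacent liver, the lipid droplet gene Cidea differed by 4.80 in the female and -1.09 in the male, 5.89 apart. The bile duct keratin Krt19 differed by 1.62 in the female and -2.39 in the male, 4.01 apart. The interferon list had medians of 0.79 in the female and -0.07 in the male, 0.86 apart. The hepatocyte list had medians of -0.40 and 0.21, a difference of -0.61. The unfolded protein response list had medians of -0.15 and 0.52, a difference of -0.67.

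Outside the genes compared, a control probe set for the B1 repeat had signals of 5574 and 3230 in the young knockout pools and 1633 and 1348 in the wild-type pools, a ratio of means of 2.95. The 6 aged knockout arrays had 1560 to 2936. Of 2369 probe sets past the filter without a single gene name, 101 were called between genotypes, 51 higher and 50 lower.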

How the results depend on the processing

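The fit with a clock score, and the list tests without a doubted array or pair, were chosen only after the result was seen. Of the values and list tests of single genes and lists under the alternatives, 7238 gene values and 520 list tests kept their direction and side of the threshold. A further 545 and 146 kept their direction but no longer passed, 211 and 9 passed anew, and 6 gene values reversed. The list tests without a doubted array or pair are not in these tallies, and some changed direction. NRF2 targets between genotypes went from a median of 0.22 to -0.26 without the wild-type female pool. Of the counts and correlations, 79 stayed within the set limits and 61 moved. Where no cause is given below, the cause was not tested.

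Between genotypes, 160 genes were called. Quantile normalization called 603 and centring on the 75th percentile 328 (232 higher, 96 lower, against 78 and 82), with the median of all genes at 0.10 rather than -0.05. Averaging probe sets called 25 and counting all probe sets 695, which tests more features. Without the intensity trend 1 was called, without the sex term 2, in 1 fit over 10 arrays 1, and with the clock score added to that fit 49 (34 of them among the 160). Leaving out 1 pool needed the fit over all remaining arrays, with the spread and sex term partly from aged tissue, and called 0 to 9, so the model and the pool changed together. The other settings called 143 to 194. In those fits Cyp8b1 ran from -3.28 to 0.40, at 0.11 (adjusted p = 0.988) without the wild-type male pool and 0.40 (adjusted p = 0.955) without the knockout female pool, while both young pairs were negative (-1.66 and -1.23).

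For HCC, 9 genes were called. Quantile normalization called 3, centring 4, no filter 16, and all probe sets 25. Without the trend 0 were called, without the mouse term 0, and in 1 fit over 10 arrays 0, where limma gave 844 at an unadjusted p below 0.05 in the paired fit. Leaving out a pair called 5 to 9 in the fit over all remaining arrays, where 1 array a side is assumed to vary like the other groups, which says nothing about stability. For all lesions, 1 gene was called. Centring called 3, no filter 3 and the 65th percentile filter 2. Averaging probe sets called 0, no mouse term 0, and 1 fit over 10 arrays 0, where 1096 had an unadjusted p below 0.05 in the paired fit. Leaving out a pair called 2 to 177, the highest without the male HCC pair.

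For adjacent aged liver against young knockout liver, 0 genes were called by limma with all arrays in every setting, with 1355 at an unadjusted p below 0.05. Leaving out an array called 0 to 441, the highest without the knockout female pool. The fit without that pool, with sex as a term, set the male HCC-adjacent array alone against the male knockout pool. Its count says nothing about stability. The fits without the male knockout pool or the male HCC-adjacent array had the female knockout pool alone as the young baseline. The range therefore does not show how the calls depend on a single array. Centring moved the median of all genes in this comparison from 0.08 to -0.10. Between the sexes, 30 genes were called. Quantile normalization called 87, averaging probe sets 18, all probe sets 86, no trend 1, no genotype term 6, and 1 fit over 10 arrays 8. Centring moved the median of all genes from 0.03 to -0.09. Leaving out a pool, in the fit over all remaining arrays, called 5 to 22. There the sex difference is averaged with aged tissue: Acnat2 ran from -0.13 to 0.34 and Cyp4a12a from -0.70 to 0.0244, against 4.38 and 2.98, and -5.17 and -2.99, in the wild-type and knockout pools at 11 weeks.

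Without the filter, which adds dim genes, the genes at least 2-fold the same way in every pair numbered 831 between genotypes, 552 between sexes, 585 in HCC and 134 in all lesions. Those in the nodule numbered 3590, and 795 under the 65th percentile filter. Correlations across genes fell to 0.215 between the genotype differences of the sexes, 0.0586 between the HCC pairs, 0.0535 between nodule and male HCC, 0.139 between nodule and female HCC, and 0.119 between the sex differences of the genotypes.

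With camera's correlation estimated, 0 lists passed between genotypes, 0 in HCC, 0 in all lesions, 0 in aged liver and 0 between sexes. With fry for a shift one way these counts were 0, 0, 0, 0 and 0. With the preset correlation the other settings passed 10 to 12, 14 to 16, 17 to 21, 8 to 13 and 5 to 7 lists in the same order, where the test without the wild-type female pool used all remaining arrays and so also changed the model. That test passed 12 lists as before, but fatty acid synthesis, CAR and PXR, and macrophage genes no longer passed, and acute phase, matrix and neutrophil genes did. The list calls were therefore made only with the preset correlation, but the alternatives do not decide whether they depend on its value. Between the sexes, female-biased genes (median 1.58) went from a camera adjusted p = 1.48e-17 to 0.914 with an estimated correlation. Their estimated correlation was -0.067, below the preset value, so a higher correlation was not the reason there. With 1 or 2 residual degrees of freedom, the absence of passing lists is weak evidence against a shift. Signals near the added constant of 16.8 carry little information, so differences of genes such as Afp in wild-type liver, at 16 and 36, are less certain than those of bright genes.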

Other observations

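The tests of CAR and PXR targets in the nodule were chosen only after the result was seen.

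Several serum amyloid and neutrophil transcripts had their highest signals in the mouse with the male HCC, in tumour and adjacent liver alike. Saa3 had signals of 35921 and 36980, and Lcn2, which sequesters bacterial iron carriers, 95466 and 87553. S100a9 had signals of 4581 and 3417 there. The neutrophil list as a whole was not raised in that mouse alone, with medians against young knockout liver of 2.50 in its adjacent liver, 1.36 in the female HCC-adjacent liver and 0.34 in the nodule-adjacent liver.

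The nodule had high signals of NRF2 targets, such as Nqo1 at 5815 against 751 in adjacent liver and Gclc at 33594 against 2214. A candidate explanation is activation of the NRF2 pathway in the nodule. Of 17 other targets set aside before being looked at, 14 were higher and 7 at least 2-fold higher, with a median of 0.92 at the 100th percentile of random lists. The random lists do not keep the correlation between genes, so correlated genes reach such a percentile more easily. Among the 17 targets were Gsr (2.51), which recycles glutathione, Tkt (2.01) of the pentose phosphate pathway, and Aox1 (1.88). The same genes had medians of -0.24 in the male HCC and -0.05 in the female HCC. CAR and PXR targets, which overlap in function, had a median of -0.18 in the nodule. Of these 17 genes 2 were at least 2-fold higher (Cyp2c55 and Abcb1a) and 2 at least 2-fold lower. The list as a whole was not raised, but it was lower in the male (-0.82) and female HCC (-0.77) too, so activation of those receptors is not excluded. With 1 nodule array and 1 adjacent array, this remains a hypothesis.

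A further hypothesis was that the changes of young knockout liver go further in the same direction in lesions. Of 159 genes called between genotypes, Gnmt left out, 100 had the same direction in lesions against adjacent liver, 62.9% against 48.8% of all genes, between the 55% and 65% set in advance. Of the 78 genes higher in young knockout liver 45 were also higher in lesions, and of the 81 lower 55 were also lower. Across all genes, which are not independent replicates, the Pearson correlation was 0.0386 and the Spearman correlation -0.0164. The share of 62.9% may reflect a partial overlap, and the test does not decide.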
